A study of Mus musculus with 6 samples.

How the data were processed

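Liver RNA of Nrf2 knockout and wild-type mice on a C57B/SV129 background was hybridised, biotin-labelled, to 1-colour Affymetrix mouse arrays. Per the labels, the mice were 10 weeks old, each array held RNA pooled from 3 animals, and RNA was extracted with phenol and chloroform and cleaned on columns. There were 6 arrays, 3 per genotype, and the genotype of each was taken from its label. The labels call the arrays of a genotype biological replicates and do not say whether any pools shared animals. The p-values measure the spread between pools, and pooling hides the spread between animals.

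The deposited values are probe set intensities on a linear scale, from 0.0174 to 16555, with no missing value. GCOS 1.4 is named per the submitters' processing notes, and the signal algorithm, scaling target and filters are not given in the sources used here. The 2% trimmed mean intensity of the arrays ran from 92.7 to 132, outside the 3% tolerance within which the table would have been taken as already scaled. Detection calls were not used here, so a low intensity has no stated limit of detection. Probe sets were named from the platform annotation, with symbols brought up to date through the Entrez identifier for 34754 probe sets and a table of mouse genes of assembly GRCm38.p6. Of the non-control probe sets, 34945 had 1 gene, 932 had several and 9160 had none here. Names were given only to probe sets with exactly 1 gene.

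Values were taken as log2(intensity + 5.26), the pseudocount being the 25th percentile of all values, and were quantile normalized between arrays. A fold change is on this scale and understates the change of dim probe sets. The 64 control probe sets were left out, and probe sets were tested whose mean log2 value reached the median, which left 22519 probe sets and 11102 genes. A gene took the statistics of its brightest tested probe set with a single gene name. Other tested probe sets of a named gene went the other way for Nfe2l2 (1 of 2 with the same sign), Hspa8 (3 of 4), Dbp (1 of 2), Hbb-b2 (1 of 2), Bpgm (2 of 3), Apoa1 (2 of 4) and Igf1 (2 of 4). The genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), with Benjamini-Hochberg adjustment over all probe sets and a threshold of 0.05. The 22518 probe sets under the filter were looked at in a fit without it, and 0 of them passed.

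There were 29 gene lists, of pathways, stress responses, sex-biased genes and cell type markers. Members under the filter were left out, so that of those with a probe set 5 of 15 pancreas and fat, 5 of 11 female-biased, 9 of 19 lymphocyte and granulocyte, 4 of 8 red blood cell, 6 of 11 cholangiocyte and 18 of 28 cell cycle genes were tested, and at most 3 were left out of any other list. Each list was tested with camera at a preset inter-gene correlation of 0.01, two-sided, adjusted over the 29 lists. Camera called 13 lists, 6 higher and 7 lower. With an estimated correlation 0 were called, the lowest adjusted p being 0.152, with 5 at an unadjusted p under 0.05. The directional fry test, which does not compare a list with other genes, called 1 list, with 7 at an unadjusted p under 0.05. The lists share some members, such as Cyp4a14, Cyp7b1 and Cyp2d9, so their results are not independent. Genes beside Nfe2l2 were the 100 tested genes on each side in the gene order of the mouse table, from which no coordinate was used. Control ratios and trimmed means were compared by exact two-sided permutation tests, for which 0.1 is the smallest p.

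Named genes followed a rule. They are Nfe2l2, then the genes past the threshold whose groups do not overlap, up to 12 with the largest increase and 12 with the largest decrease, then up to 4 members of each list with the smallest p. Nqo1, Gclc, Gclm, Gsta1, Gstm1, Insr, Igf1r, Irs1, Irs2 and Igf1 were always included where measured. The lists, this rule, the tests and all alternatives except 2 were fixed before the data were examined. A gene outside the rule is said to have been chosen after its values were seen.

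The alternatives were median centring in place of quantile normalization, a pseudocount of 1.31 or 21.0, no filter, a filter at the 70th percentile, no intensity trend, array weights, the replicate number as a block, each pool left out, the mean of a gene's probe sets, an estimated correlation, fry, and 50 or 200 neighbours on each side. Counting a gene by any of its probe sets, and leaving out each pool with no filter for the members of the female-biased list, were added after seeing the data. Median centring moved the median log2 difference of all genes from 0.01 to -0.03. The genotypes were not treated as paired.

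The procedure was tested on simulated data made with the variances of this comparison, in 5 simulations of 22519 probe sets with 200 changed. It recovered 6.71% of changes of 0.5 log2, 44.3% of changes of 1 and 89.7% of changes of 2, and 4.97% of its 423 calls were false. Of 15 lists shifted by 0.3, camera called 15, and of 120 unshifted lists it called 1, where simulated genes varied independently. Figures were drawn with matplotlib 3.10.9.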

Results

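Liver RNA of Nrf2 knockout mice was compared with liver RNA of wild-type mice of the same C57B/SV129 background, with 3 arrays per genotype and 6 in all. Nrf2, encoded by Nfe2l2, is a transcription factor that binds antioxidant response elements and drives genes of detoxification and glutathione metabolism. The mice were 10 weeks old, and each array held RNA pooled from 3 animals, so the spread between arrays is a spread between pools. The series concerns the poor liver regeneration of these animals and their resistance to insulin and IGF-1. The labels of these arrays name no injury, surgery or treatment, and no regenerating tissue was analysed here. The deposited values were linear probe set intensities, and 22519 probe sets were bright enough to be tested, standing for 11102 named genes. The 2% trimmed mean intensity per array lay between 92.7 and 132. The number of arrays, 3 per genotype, limits the precision of every comparison.

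The targeted gene was examined first. The brighter Nfe2l2 probe set had intensities of 5.74, 7.40 and 6.90 in the 3 knockout pools and of 696, 598 and 625 in the 3 wild-type pools. On the normalized log2 scale this was -5.64 ± 0.15 (SE, n = 3 per genotype), 49.8-fold lower in the knockout, with a limma adjusted p of 2.22e-06. All 6 arrays thus matched their genotype labels at this probe set. A second, dim probe set of the gene lay between 20.2 and 34.4 on all 6 arrays and did not differ (log2 difference 0.14, adjusted p = 0.92). The position of either probe set relative to the deleted part of the gene was not analysed here.

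Loss of Nrf2 went with a short list of altered transcripts, most of them lower. Of the 22519 probe sets, 32 passed an adjusted p of 0.05, 10 higher and 22 lower in the knockout, and 26 of them differed at least 2-fold. By gene, 16 of 11102 passed, 4 higher and 12 lower, with 11 differing at least 2-fold. The groups of 3 did not overlap for 1546 genes, 13.9% of those tested, where chance gives 10%. An unadjusted p under 0.05 was reached by 914 genes, 453 higher and 461 lower, where 555 would be reached by chance. Of the 32 probe sets, 26 stood for a single gene, and 6 have no single gene name here, 2 higher and 4 lower. Of the 22 genes with a called probe set, 6 were not called by their brightest one: Prm1, Tspan33, Bloc1s6, Tfpi, Haus2 and Nudt7, chosen after their values were seen. The count of probe sets was 19 without knockout pool 1, 19 without knockout pool 2 and 18 without wild-type pool 2. With all pools it was 20 with no filter, 19 with a filter at the 70th percentile and 18 without the intensity trend, where 9 genes passed.

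Over all tested transcripts, arrays of different genotype were about as alike as arrays of the same genotype. Pearson correlations across probe sets, which are not independent replicates, were 0.969 to 0.980 between knockout arrays, 0.976 to 0.984 between wild-type arrays and 0.967 to 0.983 between arrays of different genotype. The first principal component held 30.9% of the variance, and its scores were 0.33, 0.66 and -0.42 for the knockout pools and 0.03, -0.07 and -0.53 for the wild-type pools. On the second, with 25.3%, the knockout pools were at 0.04, -0.36 and -0.64 and the wild-type pools at 0.36, 0.58 and 0.03, so the genotypes overlapped there by a single pair of pools. Trimmed mean intensity was 105 ± 14.2 (SD, n = 3) in the knockout and 118 ± 21.7 in the wild type, with an exact two-sided permutation p of 0.5. The ratio of 3′ to 5′ control intensity, a sign of RNA integrity, was 0.767 and 0.760 for Gapdh (exact permutation p = 0.9). For actin this ratio was 1.97 ± 0.03 in the knockout and 1.86 ± 0.08 in the wild type, each knockout array being above each wild-type array, and the lists below were measured on these same arrays. Its exact permutation p was 0.1, the smallest that 3 against 3 can give.

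Among genes with a single name, the transcripts that fell most after Nfe2l2 itself were mainly those of drug-metabolising enzymes. Probe sets with no gene name here also fell, by 2.76 and 2.03 on the log2 scale for those that fell most, more than Abcc3. The uncharacterised gene 9130409I23Rik fell by 3.92 ± 0.35 (SE, n = 3 per genotype) on the log2 scale, 15.2-fold, with an adjusted p of 0.00297. The carboxylesterase gene Ces1g fell by 2.84 ± 0.22, 7.17-fold, and the basolateral conjugate exporter Abcc3 fell by 1.98 ± 0.27, 3.96-fold. Both aldehyde oxidase genes measured were lower, Aox1 by 3.44-fold and Aox3 by 3.13-fold, with adjusted p-values of 0.00187 and 0.000867. The malic enzyme gene Me1, a source of cytosolic NADPH, was 3.42-fold lower (adjusted p = 0.0017). The glucuronosyltransferase gene Ugt2b35 was 2.84-fold lower and microsomal epoxide hydrolase, Ephx1, was 2.46-fold lower. Smaller decreases were measured at the brightest probe sets of Gstm1 (1.94-fold), Ugt2b5 (1.68-fold) and Entpd5 (1.62-fold). Other called probe sets of Gstm1 were 3.44-fold and 2.25-fold lower. All 5 tested probe sets of Entpd5 were lower, and 1 of them passed. In the other direction, 4 genes rose in the knockout at their brightest probe set. Genes called only at a dimmer probe set also rose, chosen after their values were seen. They were Prm1, by 4.77 and 4.55 log2 at 2 probe sets (limma adjusted p = 3.37e-05 and 3.7e-05), Bloc1s6 by 1.89 and Tspan33 by 1.68. The RNA-binding protein gene Rbm45 rose by 1.95 ± 0.19 on the log2 scale, 3.87-fold (adjusted p = 0.00438). The axonemal dynein gene Dnaic1 rose 3.17-fold, the phenol sulfotransferase gene Sult1a1 1.79-fold and the mitochondrial phosphatase gene Ptpmt1 1.72-fold, each with an adjusted p of 0.0442. The calls of Sult1a1, Ptpmt1 and Entpd5 were lost without any single pool, with adjusted p up to 0.217, 0.302 and 0.161. Those of Dnaic1 and Abcc3 were lost without 5 and 4 of the 6 pools, knockout pool 2 and each wild-type pool for both and also knockout pool 1 for Dnaic1, with adjusted p up to 0.237 and 0.305, both without wild-type pool 2. Without the intensity trend these 5 and also Gstm1 and Ugt2b5 did not pass, with adjusted p from 0.0926 for Gstm1 to 0.269 for Sult1a1. Ugt2b5 also lost its call when arrays were centred on their medians (0.0936), and each of the 5 in at least 1 further setting with all pools kept.

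**Figure D1:**
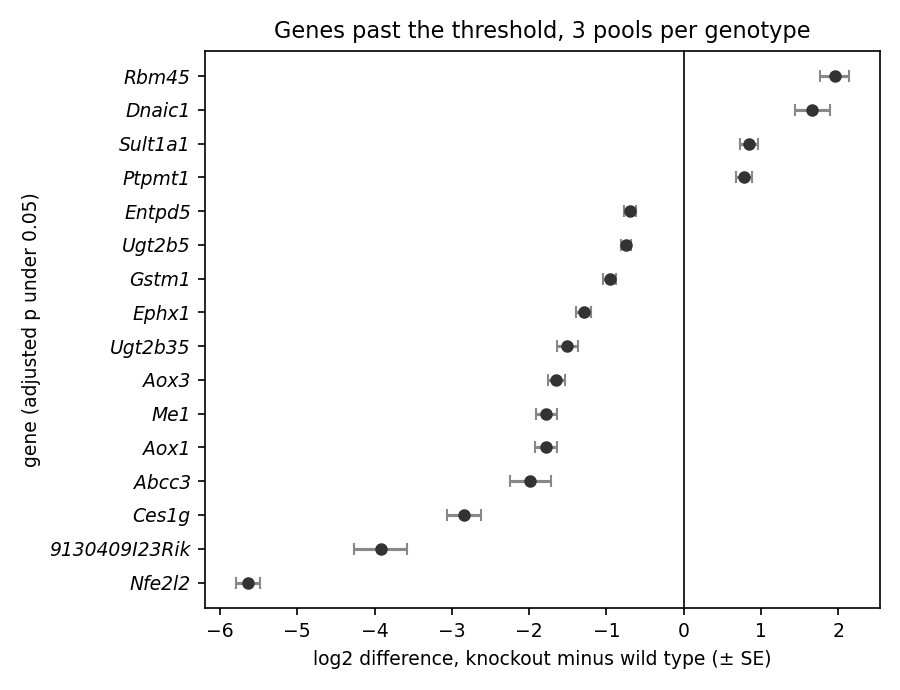
Log2 difference between Nrf2 knockout and wild-type liver (horizontal axis, knockout minus wild type, points with SE bars, 3 pools per genotype) for each of the 16 genes with an adjusted p under 0.05 (vertical axis). Each gene is shown at its brightest probe set, so genes called only at a dimmer one, Prm1 among them, are absent. Rbm45, Dnaic1, Sult1a1 and Ptpmt1 lie above 0, and the other 12 lie below 0, with Nfe2l2 at -5.64 and 9130409I23Rik at -3.92.

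Phase II and carbonyl detoxification genes, which conjugate, hydrolyse or oxidise reactive compounds, were the list that moved most clearly. Of 27 members measured above the filter, 24 were lower in the knockout, 7 fell and 1 rose, with a list median of -0.29 log2. The 7 that fell were Ces1g, Aox1, Aox3, Ugt2b35, Ephx1, Ugt2b5 and Entpd5, and the member that rose was Sult1a1, which also conjugates phenols. Adjusted over the list alone, 15 were lower and 3 higher. The camera test, adjusted over the 29 lists, gave p = 1.56e-18, against an adjusted p of 0.152 with an estimated correlation. The directional fry test gave an adjusted p of 0.0119, and no other list passed it. The actin ratio of 3′ to 5′ signal was higher on the same knockout arrays, at 1.97 against 1.86.

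Glutathione S-transferase genes, whose products conjugate glutathione to electrophiles, were lower for 13 of 19 members, but Gstm1 alone fell. Gstm1 was lower at each of its 4 probe sets, 3 of which passed. Other mu-class members were lower without passing, with log2 differences of -0.74 ± 0.11 for Gstm4, -0.61 ± 0.14 for Gstm2 and -1.04 ± 0.26 for Gstm3 (SE, n = 3 per genotype). Gstm4 and Gstm3 passed without wild-type pool 3 (adjusted p = 0.0499 and 0.0453), and Gstm4 also when arrays were centred on their medians (0.0445) or weighted (0.0359). Adjusted over the list alone, 8 members were lower and 0 higher. The list median was -0.11, -0.07 when arrays were centred on their medians and -0.06 with no filter, with a camera adjusted p of 0.000278, and an adjusted p of 0.400 with an estimated correlation. Near-identical mu-class transcripts can bind each other's probes, so the share of each member in these values is uncertain. Gsta1 was not measured here.

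Most antioxidant and glutathione synthesis genes were lower in the knockout, while the metallothionein genes were higher. Of 21 members, 17 were lower and none passed by limma; at an unadjusted p under 0.05, 5 were lower and 2 higher. Nqo1, the quinone reductase often used as a readout of Nrf2, had a log2 difference of -0.72 ± 0.22 (adjusted p = 0.493), and the groups of 3 did not overlap. Srxn1, which repairs peroxiredoxins, was at -0.45 ± 0.14 and the biliverdin reductase gene Blvrb at -0.42 ± 0.11. The glutamate-cysteine ligase genes Gclc and Gclm, which set the rate of glutathione synthesis, were at -0.18 ± 0.12 and -0.13 ± 0.11. The metallothionein genes Mt1 and Mt2, the second chosen after its values were seen, went the other way, at 2.67 ± 0.67 (adjusted p = 0.376) and 2.56 ± 0.89 (adjusted p = 0.570). Intensities of Mt1 were 339, 2208 and 2516 in the knockout pools and 219, 95.6 and 447 in the wild-type pools. Adjusted over the list alone, 1 member was lower and 1 higher. The list median was -0.15, while its mean, which takes in the metallothioneins, was 0.09. The camera test gave a lower direction with an adjusted p of 0.00466, against an adjusted p of 0.321 with an estimated correlation, and without knockout pool 1 the adjusted p was 0.0894.

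Among NADPH and pentose phosphate genes, 8 of 10 members were lower and Me1 alone fell, also when adjusted over the list alone. The transketolase gene Tkt was at -0.29 ± 0.12 log2 and the transaldolase gene Taldo1 at -0.17 ± 0.10, neither passing. The list median was -0.05, and -0.09 when arrays were centred on their medians, the camera adjusted p was 0.0263, and the adjusted p with an estimated correlation was 0.400. The call was lost without knockout pool 3 (adjusted p = 0.123) or wild-type pool 3 (0.153), without the intensity trend (0.0664) and with the replicate number as a block (0.0518). Of 16 xenobiotic transporter genes, 11 were lower and Abcc3 alone fell, also when adjusted over the list alone. The efflux pump gene Abcg2 was at -0.61 ± 0.20 and the organic anion uptake gene Slco1a4 at 0.83 ± 0.30, and the list did not pass (camera adjusted p = 0.178). Abcg2 passed without knockout pool 3, at -0.86 (adjusted p = 0.0432).

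Cytochrome P450 and nuclear receptor genes, which govern phase I oxidation, were lower for 18 of 26 members, and none passed by limma over all probe sets; at an unadjusted p under 0.05, 2 were lower and 2 higher. Cyp2c70 was at -0.40 ± 0.08 log2 and passed when adjusted over the list alone, the single member to do so. Cyp2d22 was at -0.39 ± 0.15, and Cyp2c38 and Cyp2c39 were at 0.63 ± 0.24 and 0.65 ± 0.26. The list median was -0.08, the camera adjusted p was 0.0462, and the adjusted p with an estimated correlation was 0.528. The call was lost without knockout pool 2 (adjusted p = 0.539), wild-type pool 1 (0.196), wild-type pool 2 (0.0669) or wild-type pool 3 (0.0526), and when arrays were centred on their medians (0.173) or all probe sets were tested (0.176). It was also lost with a filter at the 70th percentile (0.0788), no intensity trend (0.128), array weights (0.0566), the replicate number as a block (0.0525) and the mean of probe sets (0.165).

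Proteasome subunit genes were higher in the knockout for 28 of 31 members, by small amounts. The list median was 0.11 log2, and 0.07 when arrays were centred on their medians, and the members with the smallest p-values were Psmb3 at 0.26 ± 0.09, Psma5 at 0.24 ± 0.09, Psma7 at 0.23 ± 0.09 and Psmd4 at 0.21 ± 0.08. None passed by limma over all probe sets or adjusted over the list alone, and 5 had an unadjusted p under 0.05, all higher. Camera gave an adjusted p of 4.78e-05, against 0.214 as the adjusted p with an estimated correlation and 0.0619 as the adjusted p by fry. On the same arrays the actin ratio of 3′ to 5′ signal was higher in the knockout, at 1.97 against 1.86. Amino acid and endoplasmic reticulum stress genes were lower for 17 of 19 members, with a median of -0.23. The chaperone genes Sdf2l1 and Pdia4 were at -0.67 ± 0.25 and -0.57 ± 0.22, and 0 members passed by limma over all probe sets or adjusted over the list alone, with 2 at an unadjusted p under 0.05. By camera the adjusted p was 0.00147, and the adjusted p with an estimated correlation was 0.475. Heat shock chaperone genes, led by Hspe1 at 0.26 ± 0.13 and Hspa8 at -0.42 ± 0.31, had 11 of 14 members lower and did not pass (camera adjusted p = 0.540), with 0 members passing by limma or at an unadjusted p under 0.05. Without knockout pool 3 this adjusted p was 1.5e-05 and without wild-type pool 1 it was 0.0457, with the members on balance lower.

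The insulin and IGF-1 signalling genes, the pathway named by the series, did not differ as a group between the genotypes. Of 38 members measured, 19 were higher and 19 lower, with a median of 0.00 log2 and a camera adjusted p of 0.874. None passed by limma over all probe sets; at an unadjusted p under 0.05, 3 were higher and 1 was lower. The insulin receptor gene Insr was at 0.14 ± 0.10 and the IGF-1 receptor gene Igf1r at 0.25 ± 0.20 (SE, n = 3 per genotype). The receptor substrate genes Irs1 and Irs2 were at 0.40 ± 0.11 (adjusted p = 0.455) and 0.66 ± 0.27 (adjusted p = 0.630), and Igf1 was at -0.03 ± 0.09, with 2 of its 4 probe sets lower. Adjusted over the list alone, Grb10, an adaptor that binds both receptors, was lower at -0.69 ± 0.14, and Igfbp2, an IGF-binding protein gene, was higher at 0.67 ± 0.14. The arrays measured transcripts, so phosphorylation of these proteins lies outside the data.

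Genes of glucose and lipid synthesis did not move as groups. In gluconeogenesis and glycolysis, 8 of 17 members were higher and 9 lower (camera adjusted p = 0.578), with the coactivator gene Ppargc1a at 0.79 ± 0.24 and the glucokinase regulator gene Gckr at 0.35 ± 0.12. In fatty acid and triglyceride synthesis, 10 of 23 were higher and 13 lower (camera adjusted p = 0.312), with Pparg at -1.28 ± 0.39 and the desaturase gene Fads2 at 0.44 ± 0.14. In cholesterol synthesis, 7 of 18 were higher and 11 lower (camera adjusted p = 0.540, but 0.00179 without knockout pool 2), with Mvd at -0.50 ± 0.12. In bile acid synthesis, 6 of 15 were higher and 9 lower (camera adjusted p = 0.979). There the oxysterol hydroxylase genes moved apart, Cyp39a1 at 1.47 ± 0.42 and Cyp7b1 at -1.11 ± 0.28, and the nuclear receptor gene Nr5a2 was at 0.49 ± 0.11. No member of these 4 lists passed by limma over all probe sets. At an unadjusted p under 0.05, gluconeogenesis and glycolysis had 2 higher and 4 lower, fatty acid synthesis 2 and 2, cholesterol synthesis 1 and 1, and bile acid synthesis 2 and 1. Adjusted over the list alone, Cyp39a1 and Nr5a2 were higher and Cyp7b1 lower, and 0 members of the other 3 lists passed.

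Fatty acid oxidation and PPARα target genes were higher for 18 of 27 members, and none passed by limma over all probe sets or adjusted over the list alone. At an unadjusted p under 0.05, 7 members were higher and 0 lower. The omega-hydroxylase gene Cyp4a14 was at 3.67 ± 0.93 log2 (adjusted p = 0.391), with intensities of 60.7, 392 and 2051 in the knockout pools and of 31.9, 14.0 and 40.9 in the wild-type pools. It was at 2.54 without knockout pool 3, and without knockout pool 1 it passed, at 4.88 (adjusted p = 0.0419). Ehhadh and Hadha, both of beta-oxidation, were at 0.31 ± 0.09 and 0.25 ± 0.08. The list median was 0.07, and 0.04 when arrays were centred on their medians, the camera adjusted p was 0.0235, and the adjusted p with an estimated correlation was 0.679. The call was lost without knockout pool 3 (adjusted p = 0.736), and with all pools kept it was lost without the intensity trend (0.0671), with array weights (0.0566) and with the mean of probe sets (0.0665).

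Genes with sex-biased expression in mouse liver moved in opposite directions. Of 11 female-biased genes with a probe set, 5 were above the filter, and these 5 were higher in the knockout, with a median of 1.59 log2. The filter takes the mean of all arrays, so high knockout values help a dim gene pass it. With no filter 10 of the 11 were higher and 1 lower, with a median of 0.61 (camera adjusted p = 0.00216). The members under the filter, listed after their values were seen, moved less clearly. Sult3a1, Cyp3a16 and Cyp3a44 were at 0.02, 0.01 and 0.09, Xist at 0.27, Cyp2b9 at 0.61 and Cyp2b13 at -0.52. Their limma unadjusted p ran from 0.139 to 0.955, so the shift of this list rests on the 5 members above the filter. Cyp17a1, a steroid hydroxylase gene, was at 2.49 ± 0.40 (adjusted p = 0.0885, and 0.0131 with the replicate number as a block), Acot3 at 1.59 ± 0.55 and Hao2 at 1.29 ± 0.64. Intensities of Cyp17a1 were 124, 284 and 128.5 in the knockout pools and 43.4, 30.1 and 16.4 in the wild-type pools. The difference at Hao2 rested on knockout pool 2, with intensities of 13.3, 104 and 15.2 in the knockout and of 15.6, 9.61 and 5.52 in the wild type, and it was 0.44 without that pool in a fit with no filter. At Acot3 it was 0.95 without wild-type pool 1. The remaining member, Cux2, listed after its values were seen, was at 0.87 ± 0.46 in a fit with no filter, and at 0.26 without wild-type pool 2. With all pools and no block none passed by limma over all probe sets, 3 had an unadjusted p under 0.05, and adjusted over the list alone these 3, Cyp17a1, Cyp4a14 and Acot3, were higher. Of 13 male-biased genes, 12 were lower, with a median of -0.22, Cyp7b1 leading, Cyp4a12a at -0.73 ± 0.26 and Elovl3 at -0.44 ± 0.19. The list also holds Y-linked genes, and the brightest probe sets of Eif2s3y, Uty and Kdm5d were at -0.22, -0.09 and -0.03. None passed over all probe sets, 3 had an unadjusted p under 0.05, and 1, Cyp7b1, was lower when adjusted over the list alone. The camera adjusted p was 3.88e-05 for the female-biased list and 0.000779 for the male-biased list. With an estimated correlation the adjusted p was 0.152 and 0.359.

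**Figure D2:**
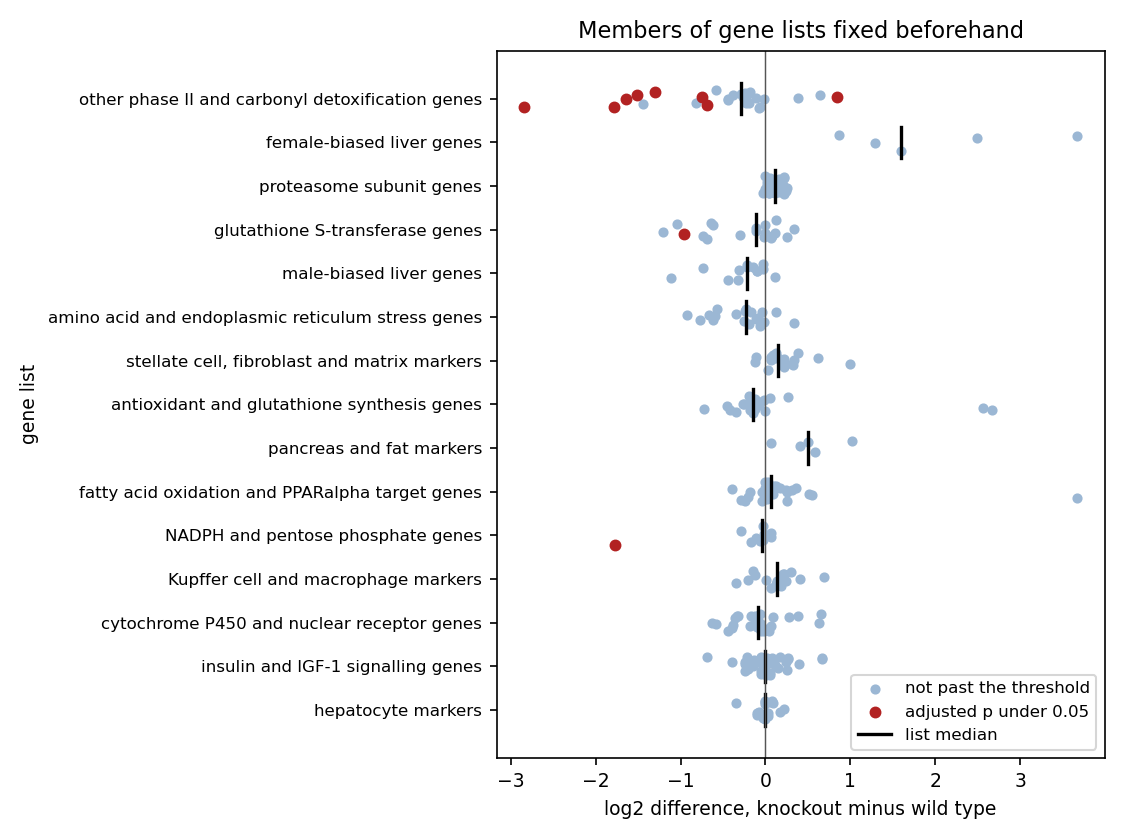
Log2 difference, knockout minus wild type (horizontal axis), of each member above the filter (points, 3 pools per genotype) of the 13 gene lists with a camera adjusted p under 0.05 and of the insulin and hepatocyte lists (vertical axis); black bars are list medians and red points passed an adjusted p of 0.05. The phase II list has its median at -0.29 and 8 red points, the 5 female-biased genes above the filter, of 11 with a probe set, lie above 0 with their median at 1.59, and the insulin list is spread evenly around 0.

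Markers of other cell types were in part higher in the knockout, while hepatocyte markers did not shift. Of 17 hepatocyte genes, 8 were higher and 9 lower, with a median of 0.00 that changed sign when arrays were centred on their medians (camera adjusted p = 0.681), and Hpd and Glul were at 0.17 ± 0.06 and -0.35 ± 0.21. Stellate cell, fibroblast and matrix markers were higher for 17 of 19 members, with a median of 0.15, desmin (Des) at 1.00 ± 0.31 and lumican (Lum) at 0.38 ± 0.12. The camera adjusted p was 0.00408, against an adjusted p of 0.214 with an estimated correlation and of 0.0647 without wild-type pool 2. Kupffer cell and macrophage markers were higher for 13 of 17, with Mpeg1 at 0.68 ± 0.18 and lysozyme (Lyz2) at 0.41 ± 0.15. The camera adjusted p was 0.0456, and the adjusted p with an estimated correlation was 0.761. The call was lost without knockout pool 1 (adjusted p = 0.659), wild-type pool 1 (0.293) or wild-type pool 2 (0.110), without the intensity trend (0.0818) and with the replicate number as a block (0.0605). Of 15 pancreas and fat markers with a probe set, 5 were measured above the filter and these 5 were higher, among them lipoprotein lipase (Lpl) at 1.02 ± 0.35 and the elastase gene Cela2a at 0.59 ± 0.23. Their camera adjusted p was 0.0123, and the adjusted p with an estimated correlation was 0.243. This call depended on the filter, with an adjusted p of 0.235 with no filter and 0.0987 with a filter at the 70th percentile. No marker in these lists passed by limma over all probe sets or adjusted over the list alone; at an unadjusted p under 0.05 were 2 stellate, 3 Kupffer, 2 pancreas or fat and 1 hepatocyte marker, all higher. The actin ratio of 3′ to 5′ signal, 1.97 against 1.86, was higher on the same arrays.

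The remaining cell type lists did not pass. Sinusoidal endothelial markers were higher for 10 of 16, with Ptprb at 0.22 ± 0.09 (camera adjusted p = 0.255) and a median that changed sign when arrays were centred on their medians. Lymphocyte and granulocyte markers were higher for 7 of 9, with Ngp at 0.61 ± 0.37 (camera adjusted p = 0.261, and 0.00163 without knockout pool 3). Of 6 cholangiocyte markers, 2 were higher and 4 lower (camera adjusted p = 0.846), with Krt8 at -0.26 ± 0.09 and Pkhd1 at 0.45 ± 0.16. Of 4 red blood cell markers, 2 were higher and 2 lower (camera adjusted p = 0.573), with Hbb-b2 at 0.54 ± 0.24 and a median that also changed sign with that centring. In these 4 lists 0 members passed by limma over all probe sets or adjusted over the list alone. At an unadjusted p under 0.05 were 1 endothelial marker, higher, and 2 cholangiocyte markers, 1 higher and 1 lower.

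Proliferation, inflammation and clock genes did not pass as groups either. Cell cycle genes were higher for 12 of 18 members, with the cyclin gene Ccnd1 at 0.65 ± 0.23 and the replication helicase gene Mcm6 at 0.67 ± 0.25. Their camera adjusted p was 0.0973, and it was 0.0289 without knockout pool 1, 0.0105 without knockout pool 3, 0.0281 without wild-type pool 3 and 0.0336 when arrays were centred on their medians. Acute phase genes were higher for 17 of 24, with Orm3 at -1.67 ± 0.47 and Il1rn at 1.05 ± 0.33 (camera adjusted p = 0.287, and 9e-04 without wild-type pool 3). Interferon and antigen presentation genes were higher for 12 of 23, led by the MHC class II genes H2-Eb1 at 0.60 ± 0.16 and Cd74 at 0.48 ± 0.14 (camera adjusted p = 0.287, and 0.0146 without knockout pool 3). Circadian clock genes were lower for 11 of 15, with Per2 at -0.50 ± 0.30 and Dbp at -0.58 ± 0.37 (camera adjusted p = 0.287). No member of these 4 lists passed by limma over all probe sets or adjusted over the list alone. At an unadjusted p under 0.05, cell cycle genes had 3 higher and 1 lower, acute phase genes 1 and 2, interferon genes 3 and 0, and clock genes 0.

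Genes beside Nfe2l2 were examined because a targeted allele can bring flanking DNA of the strain it was made in. Among the 200 tested genes nearest to it, 100 on each side, 2 were past the threshold, Rbm45 at 4 genes away and Ptpmt1 at 44 genes away. Each had 1 tested probe set, so a strain base difference under its probes and a change in level cannot be told apart. Elsewhere 13 of 10901 genes passed, an odds ratio of 8.46 with a two-sided Fisher exact p of 0.0291. The camera test of the neighbours as a set, which is part of limma and not an exact test, gave p = 0.408. Camera looks for a shift of the set in 1 direction, so it cannot speak to neighbours that move both ways. A limma unadjusted p under 0.05 was reached by 24 of the 200, against 914 of all 11102 genes, and these shares were not compared by a test. With 1 of the 200 passing, the Fisher exact p was 0.211 without knockout pool 1, 0.196 without knockout pool 2, 0.196 without wild-type pool 1 and 0.225 without wild-type pool 3. Again 1 of 200 passed when arrays were centred on their medians (Fisher exact p = 0.266), with no filter (0.115), a filter at the 70th percentile (0.248), no intensity trend (0.135) and the replicate number as a block (0.292). With 200 neighbours on each side the p was 0.0999, and over all alternatives the p ran from 0.00271, for the mean of probe sets with 3 of 200, to 0.292.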

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

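The counts, the list tests, the neighbour tests and the genes named by rule were repeated under the alternatives that apply to each, of which counting a gene by any of its probe sets was chosen after seeing the data and gave 22 genes against 16. The calls of Nfe2l2, Rbm45, 9130409I23Rik, Ces1g, Aox1, Me1, Aox3, Ugt2b35 and Ephx1 were kept in all 15 alternatives run for each. Gstm1 kept its call in 14, Ugt2b5 in 13, Entpd5 in 7, Dnaic1 in 7 of 14, Abcc3 in 6, and Sult1a1 and Ptpmt1 in 4 each. No called result among these reversed. Called probe sets of other genes, the count on chromosome 2 and the family scan were not repeated in this way, apart from a centred median and an estimated correlation for the families. Of 319 list results apart from left-out pools, 277 kept their side of the threshold, 41 lost their call and 1 gained it. Of these 319, 6 differed in sign, each in a list not past the threshold. Of 1875 results of the other named genes, 1819 kept their side, 49 lost their call and 7 gained it.

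Against 32 probe sets, 20 passed with no filter, 19 with the filter at the 70th percentile and 18 without the intensity trend, and 9 genes passed without the trend against 16. The P450 list lost its call with median centring (adjusted p = 0.173), no filter (0.176), the 70th percentile (0.0788), no trend (0.128), array weights (0.0566), and the mean of probe sets (0.165). The fatty acid oxidation list lost it with no trend (0.0671), weights (0.0566) and the mean of probe sets (0.0665). The pancreas and fat list lost it with no filter (0.235) and the 70th percentile (0.0987). Without the trend the NADPH list was at 0.0664 and the Kupffer list at 0.0818. The cell cycle list gained a call with median centring (0.0336). The share of called genes beside Nfe2l2 no longer passed, with a Fisher exact p of 0.266 under median centring, 0.115 with no filter, 0.248 at the 70th percentile, 0.135 with no trend and 0.0999 with 200 neighbours on each side. The cause of these changes was not tested.

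With an estimated correlation the adjusted p was 0.152 for phase II and for female-biased genes, 0.214 for proteasome and stellate genes, 0.243 for pancreas and fat, 0.321 for antioxidant, 0.359 for male-biased, 0.400 for glutathione S-transferase and NADPH, 0.475 for amino acid and endoplasmic reticulum stress, 0.528 for P450, 0.679 for fatty acid oxidation and 0.761 for Kupffer genes. With fry it was 0.0619 for proteasome, female-biased, and pancreas and fat genes, 0.170 for NADPH, 0.189 for stellate, 0.202 for antioxidant and glutathione S-transferase, 0.276 for male-biased, 0.524 for stress, 0.528 for P450, 0.616 for fatty acid oxidation and 0.740 for Kupffer genes.

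The labels give both genotypes replicate numbers 1 to 3 without saying that a number is shared. Deviations from the group mean correlated at 0.13, 0.05 and 0.25 for equal numbers, not above 0.1 for each pair, and knockout pool 2 correlated best with wild-type pool 1. With the replicate number as a block 32 probe sets and 20 genes passed, and adjusted p was 0.0518 for NADPH, 0.0525 for P450 and 0.0605 for Kupffer genes, with 0.292 for the share beside Nfe2l2. Cyp17a1 gained a call with this block (adjusted p = 0.0131).

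Leaving out 1 pool at a time gave 18 to 29 probe sets and 12 to 18 genes, both lowest without wild-type pool 2 and highest without knockout pool 3. The lists whose side of the threshold depended on a pool had adjusted p from 0.000466 (without wild-type pool 3) to 0.0894 (knockout pool 1) for antioxidant, 0.00365 (wild-type 2) to 0.153 (wild-type 3) for NADPH, 0.0243 (knockout 3) to 0.539 (knockout 2) for P450, 0.000249 (knockout 2) to 0.736 (knockout 3) for fatty acid oxidation, 0.000778 (knockout 3) to 0.659 (knockout 1) for Kupffer, and 0.000466 (wild-type 3) to 0.0647 (wild-type 2) for stellate genes. Of lists not called with all pools, the range was 0.00179 (knockout 2) to 0.924 (wild-type 1) for cholesterol, 0.0105 (knockout 3) to 0.853 (knockout 2) for cell cycle, 9e-04 (wild-type 3) to 0.957 (knockout 3) for acute phase, 0.0146 (knockout 3) to 0.595 (wild-type 2) for interferon, 1.495e-05 (knockout 3) to 0.616 (knockout 1) for heat shock, and 0.00163 (knockout 3) to 0.899 (knockout 2) for lymphocyte genes. The Fisher exact p beside Nfe2l2 ran from 0.0160 (wild-type 2) to 0.225 (wild-type 3). Of 174 list results with a pool left out, 153 kept their side, 12 lost and 9 gained a call, and 19 differed in sign, each in a list not past the threshold. Members of the female-biased list were also fitted without each pool and with no filter, a choice made after seeing the data, and Hao2 ran from 0.44 (knockout 2) to 1.73 (knockout 3). A fit without a pool has fewer arrays, and no other cause was tested.

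Dim probe sets limit the folds, since detection calls were not used here. The difference at Nfe2l2 was -6.20 log2 with the pseudocount of 1.31 and -2.75 for the mean of its probe sets, which takes in the dim one.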

Other observations

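The tests of gene families, Prm1, chromosome 2 and sex-biased genes were chosen after the result was seen, as were the gene symbols that appear here and not in the results, and the count of other splits was planned. Gene families were formed from symbols that share a stem, and the 177 families with at least 8 tested genes were scanned with camera, which gave 9 an adjusted p under 0.05 and, with an estimated correlation, 0. Glucuronosyltransferase genes (Ugt) were lower for 9 of 10 members, with a median of -0.47 log2 and an adjusted p of 1.02e-11. Ugt2b38 was at -1.06 ± 0.16 (SE, n = 3 per genotype, limma adjusted p = 0.0741). Carboxylesterase genes (Ces) were lower for 9 of 12, with a median of -0.51 and an adjusted p of 7.18e-07, Ces1f being at -1.41 ± 0.21 and Ces2b at -2.54 ± 0.51. Both families overlap the phase II list, and near-identical members can share probes. With an estimated correlation the adjusted p was 0.881 for each. Medians kept their sign with median centring, at -0.48 and -0.56.

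The other 7 families moved by small amounts. All 12 measured genes of the Ndufa stem, subunits of mitochondrial complex I, were higher in the knockout, with a median of 0.17 and 0.14 after median centring. Genes of the Sec stem, many of which act in protein secretion, were lower for 22 of 25, with a median of -0.14. The camera adjusted p was 0.000167 for both families, and the adjusted p with an estimated correlation was 0.962. No member of either family passed by limma over all probe sets. Genes of the Akr stem, some of them in the phase II list, were lower for 11 of 13 (adjusted p = 0.00603). Higher were 36 of 47 for Mrpl (0.00915), 15 of 22 for Cox (0.0173), 23 of 26 for Rps and 38 of 51 for Atp (0.0407 for both), and the Mrpl median of 0.07 was 0.01 after median centring. For these 5 the adjusted p with an estimated correlation was also 0.962.

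The arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 32 probe sets and 16 genes, and the highest of the other splits gave 0 of each, so 1 of 10 splits gave as many. It gave 13 gene lists, also reached by 1 of 10 splits. The split of knockout pools 1 and 2 with wild-type pool 3 against the rest gave 12 lists, however. Each of the remaining splits, in which the genotypes are also mixed, gave from 5 to 9 lists. Camera at the preset correlation thus called lists under every wrong grouping. Of the 13 lists, 6 had their smallest p in the real split: glutathione S-transferase, phase II, proteasome, female-biased, male-biased, and pancreas and fat genes. Of the other 7, splits with a p as small, the real one included, were 2 of 10 for antioxidant, NADPH and stellate genes, 3 for stress, 4 for P450, 5 for fatty acid oxidation and 6 for Kupffer genes. Another split gave a p of 2.91e-11 for stress genes against 0.000304 in the real one, and of 2.65e-10 for Kupffer genes against 0.0189.

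The testis gene Prm1, which packs sperm DNA, had the largest increase of any tested probe set. At 2 of its 3 probe sets the log2 difference was 4.77 and 4.55 (limma adjusted p = 3.37e-05 and 3.7e-05), with mean normalized intensities of 146 and 126 in the knockout and of 0.284 and 0.295 in the wild type. Germ cell RNA as a source is argued against by Prm2, Tnp1 and Tnp2, as abundant as Prm1 in spermatids, whose highest knockout mean was 2.67, and 0 of 14 probe sets of 8 germ cell genes had an unadjusted p under 0.05. A candidate explanation is that the targeted allele carries part of Prm1, whose 3′ end is used in some gene constructs. The third probe set, already at a mean of 131 in the wild type, gained 74.8 ± 37.3 (SE) against 125 and 146. It did not pass (log2 0.69, limma adjusted p = 0.611). Since probe positions were not used here, a probe set inside such a part and one outside it cannot be told apart.

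Genes with a called probe set lay on chromosome 2, that of Nfe2l2, more often than tested genes did: 5 of 21 against 7.76% of 11086, Nfe2l2 left out (odds ratio 3.73, Fisher exact p = 0.0199). They are Rbm45, Tfpi, Ptpmt1, Haus2 and Bloc1s6, at 4, 24, 44, 170 and 194 tested genes from it, and this is consistent with DNA of another strain carried along, although the p adjusted over 23 such tests, which include the mitochondrial genome and 1 gene of unknown place, was 0.332, equal for chromosome 1 with 4 genes. A base difference under single probes is argued against for Tfpi, where the other 3 probe sets were also lower with an unadjusted p under 0.05 (log2 -0.97 to -1.23). For Rbm45 and Ptpmt1, with 1 tested probe set each, such a difference could not be checked. For Bloc1s6, where 0 of 2 others moved with it (log2 -0.05 and -0.22 against 1.89), such a difference is a candidate explanation, and for Haus2, with 1 of 3 lower and 1 higher (0.45, unadjusted p = 0.0187), it and a change in level cannot be told apart. A regulatory effect of Nrf2 on these genes stays open and was not tested.

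The shift of sex-biased genes, higher female-biased and lower male-biased, could come from females among the knockout pools, as the labels used here give no sex. With 1 female among the 3 animals of each pool, Y-linked genes, some of them in the male-biased list, would be at -0.58 log2. Used here were the 6 tested probe sets of Eif2s3y, Kdm5d and Uty, without their dimmer ones under the filter and without other Y-linked genes. Their median was -0.0636, which argues against a female in each pool. These 6 ran from -0.22 to 0.26, and their SD of 0.17 is a spread between probe sets, not an error of the genotype difference. A female in a single knockout pool would lower these values less and was not tested. The 3 Xist probe sets had intensities of at most 13.9 on any array. Of these, 1 was higher in the knockout (log2 0.59, limma unadjusted p = 0.0447), at intensities of at most 5.17. PPARα targets, Cyp4a14 and Acot3 among them, are another candidate for the female-biased list. No male-biased gene is in the PPARα list, but that list also lacks Acot3, so whether PPARα acts on male-biased genes was not tested. Without Cyp4a14 and Acot3 the female-biased list kept 3 members, Cyp17a1, Hao2 and Cux2. Their camera p was 0.000403 and their median was 1.29, which was Hao2. That median became 0.85 without knockout pool 2, and 3 genes are too few to exclude this candidate. Without knockout pool 3 the fatty acid oxidation and PPARα list was at an adjusted p of 0.736, while both sex-biased lists were at 7.49e-05. Cyp4a14 and Acot3 were still at 2.54 and 1.74 log2 without that pool, in a fit with no filter, so this contrast cannot separate the candidates. A regulatory effect of Nrf2 on the sex-biased genes stays open and was not tested, and with an estimated correlation neither sex-biased list passed.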
